A study of Mus musculus with 13 samples.

How the data were processed

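The deposited table holds raw read counts per gene symbol, with 1 column for each of the 13 samples. Per the submitters' processing notes, STAR 2.4, HTSeq 0.6.1, DESeq2 and the mouse build mm10 (GRCm38) were used before these counts were deposited, but the role of each tool is not given. The annotation release, the strand setting of the counting and any trimming are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. Per the labels' protocols, tumours were dissociated with papain, GFP-positive cells were sorted and libraries were made with a TruSeq RNA kit, from pellets of 1 to 5 M cells for primary tumours and 0.1 to 3 M cells for metastases. The files state no unique molecular identifiers, so the counting intervals below cover counting error only and not amplification.

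The table has 53653 genes, of which 47744 had a count in at least 1 library, and no column without a sample. Gene symbols were matched to GENCODE M21 for coordinates on GRCm38, which are printed 1-based. Of all symbols 28534 matched, and of the 22265 tested 15811 did. Clone names such as RP23-95H5.1 had no coordinates. Some genes that the rule below takes are not reported here. Reads shared between near-identical genes could not be assigned from counts, so the levels of Tpm3-rs7, H2-Q7 and mitochondrial genes with nuclear copies are uncertain.

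All 13 libraries were fitted together with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with quasi-likelihood F tests for the 3 groups. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Levels are TMM-scaled CPM with SD over libraries, except the receptor and Rn18s-rs5 levels, which are CPM of the unscaled totals. The log2 changes carry the standard error of the fitted coefficient.

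Gene lists were tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and adjusted over 42 lists, 26 of genes and 16 of markers of cell types. Each list was also tested with a correlation estimated from the data and with fry. Within a list, the members were called both over all genes and with their p-values adjusted over the list alone. A list was tested where at least 3 members were measured.

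The lists, the comparisons, the rule for the genes named and the first set of alternatives were chosen before the data were examined. The rule names Kmt2d and Smo, and for each comparison the 12 called genes with the largest rises and the 12 with the largest falls. For these, a mean of at least 5 CPM, no overlap between the groups and a symbol other than a predicted gene or a gene used to read sex were required. It adds the 4 members with the smallest p of each called list and up to 2 of each other list. The alternatives added after the data were seen leave out the 4 libraries above 100 receptor CPM, use the receptor level as a covariate or leave out the 3 controls with Xist counts.

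A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with its 95% counting interval is given. In simulated counts with the means and totals of these libraries, 300 genes of at least 1 CPM changed by 2-fold were recovered in 40.3% of cases for KO primary against control primary, 35% for KO metastasis against KO primary and 31.3% for KO metastasis against control primary. For 300 genes changed by 4-fold the shares were 78.3%, 75.7% and 75%, respectively. These runs covered 22262, 22265 and 22262 genes. DESeq2 1.42.0 and limma voom with quality weights were run as alternatives.

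For the overlap of both knockout groups, the expected number is the product of the called numbers in each direction divided by the number of genes. Unchanged groups were simulated 20 times against the same controls, and the controls were divided between the comparisons in 20 ways.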

Results

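Gene counts were analysed for 13 RNA-seq libraries of GFP-positive cells sorted from mouse medulloblastomas, cerebellar tumours driven here by SmoM2, a constitutively active form of Smoothened that switches on the Sonic Hedgehog pathway. There were 5 libraries from primary cerebellar tumours with intact Kmt2d (control primary, replicates 3 to 7), 4 from primary tumours with Kmt2d knocked out (KO primary, replicates 3, 4, 6 and 7) and 4 from spinal metastases with the knockout (KO metastasis, replicates 3, 4, 6 and 7). KMT2D is a histone H3 lysine 4 methyltransferase that acts mainly at enhancers. Per the labels, control mice were 6 to 16 weeks old and knockout mice 5 to 8 weeks. The labels do not say which libraries came from separate mice, so every edgeR p-value measures the spread between these libraries. A camera p-value with the preset correlation sets the genes of a list against all other genes. It is no measure of that spread.

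Total counts were 23.5, 34.1, 24.9, 31.7 and 37.5 M in control primary replicates 3 to 7 (mean 30.3 ± 5.96 M, SD). KO primary replicates 3, 4, 6 and 7 held 41.4, 38.1, 38.5 and 35.2 M (38.3 ± 2.54 M). KO metastasis replicates 3, 4, 6 and 7 held 29.4, 40.8, 27.1 and 34.2 M (32.9 ± 6.07 M). Olfactory and vomeronasal receptor genes, which cerebellar cells do not use, drew 1752 CPM (counts scaled to the library total) in control primary 3, 723 CPM in KO primary 7, 565 CPM in KO metastasis 6 and 349 CPM in KO metastasis 7. They drew 83.5 CPM in KO primary 6 and between 6.08 and 19.5 CPM in the other 8 libraries. The 4 libraries above 100 CPM are called high-background libraries from here on. KO metastasis 3 stood apart by a share of 2.06% of counts on mitochondrially encoded genes, against 0.745% to 0.860% in the other metastases. Xist was at 330 to 483 CPM in control primary 5, 6 and 7 and at 0.913 CPM or below in the other 10 libraries. Ddx3y, on the Y chromosome, was at 55.1 to 121 CPM in those 10 and at 0 in control primary 5, 6 and 7. Every KO library was therefore male by expression, and the controls were mixed in sex.

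**Figure D1:**
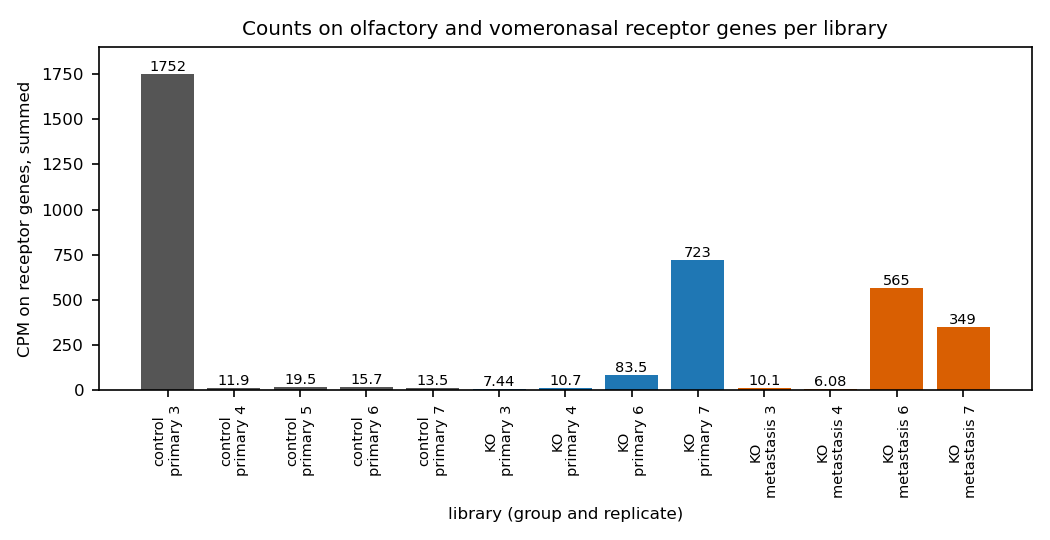
Summed CPM on the 1982 olfactory and vomeronasal receptor genes (vertical axis) in each of the 13 libraries (horizontal axis), coloured by group. Control primary 3 reached 1752 CPM, KO primary 7 723 CPM, KO metastasis 6 565 CPM and KO metastasis 7 349 CPM, and KO primary 6 came next with 83.5 CPM.

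The knocked-out gene was read first. Kmt2d (GRCm38 chromosome 15, 98831669 to 98871204, protein coding) was at 78.1, 104.5, 175.0, 129 and 141 CPM in control primary 3 to 7. It was at 91.7, 93.0, 111 and 168 CPM in KO primary 3, 4, 6 and 7, and at 115, 104.7, 111 and 131 CPM in KO metastasis 3, 4, 6 and 7. The group means of 125 ± 36.7, 116 ± 35.7 and 115 ± 11.2 CPM gave edgeR adjusted p = 0.956 for KO primary and 0.945 for KO metastasis against control primary. These are counts over the whole gene, which do not resolve the loss of part of it. The deleted part is not given in the sources used here, so this level does not check the genotype labels. Smo (chromosome 6, 29735503 to 29761365) was at 272 ± 54.5 CPM in control primary, 347 ± 69.1 CPM in KO primary and 282 ± 95.5 CPM in KO metastasis libraries, with no call in any comparison (lowest edgeR adjusted p = 0.583).

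The first comparison asked how loss of Kmt2d changes primary tumours. Genes of differentiating granule neurons were lower in KO primary than in control primary tumours. Tubb3, a neuronal tubulin, fell from 633 ± 167 CPM (SD, n = 5) to 195 ± 43.1 CPM (n = 4), a log2 change of -1.70 (SE 0.245, edgeR adjusted p = 0.00199). Neurod1, a transcription factor of neuronal differentiation, fell from 567 ± 186 to 162 ± 41.2 CPM. Ccnd1, the cell cycle gene for cyclin D1, rose from 338 ± 28.0 to 544 ± 67.6 CPM (log2 change 0.69, SE 0.123, edgeR adjusted p = 0.00783). Atoh1, the transcription factor that defines granule cell precursors, rose from 350 ± 49.9 to 684 ± 83.3 CPM (edgeR adjusted p = 0.0199). In all, 653 of 22265 tested genes changed at an edgeR adjusted p below 0.05, 257 higher and 396 lower. Of these, 484 changed by at least 2-fold (171 higher, 313 lower). At an unadjusted p below 0.05 there were 3020 genes, where chance gives 1113.

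In the list of early granule neuron differentiation genes, all 20 were measured, 11 fell, none rose and 9 were not called. Adjusted over the list alone, 13 fell and 1 rose. The median log2 change was -0.96 (camera adjusted p = 2.4e-19). This was the 1 list of this comparison called again with an estimated correlation (camera adjusted p = 0.0334 with an estimated correlation). Elavl4 (chromosome 4, 110203722 to 110351909), a neuronal RNA-binding protein, fell from 178 ± 23.2 to 79.1 ± 6.52 CPM (log2 change -1.17, SE 0.134, edgeR adjusted p = 4.57e-04). Stmn2, a stathmin of growing axons, fell from 286 ± 68.3 to 99.2 ± 25.9 CPM. Tubb3 (chromosome 8, 123411424 to 123422015) and Neurod1 (chromosome 2, 79452521 to 79456751) are among the 11. These 4 genes kept an edgeR adjusted p below 0.05 whichever library was left out. Mature granule neuron and synapse genes went the same way, with 4 of 25 members lower, 1 higher and 20 not called (9 lower and 1 higher adjusted over the list alone). Their median was -0.96 (camera adjusted p = 2.23e-07, but adjusted p = 0.354 with an estimated correlation). Syp, the synaptic vesicle protein synaptophysin, fell from 86.0 ± 20.2 to 32.0 ± 4.99 CPM (edgeR adjusted p = 6.33e-04). Snap25, a protein of vesicle fusion, fell from 243 ± 63.7 to 102 ± 17.6 CPM (edgeR adjusted p = 0.00505). Cbln1, a synapse organiser of granule cells, went against the list and rose from 34.4 ± 4.96 to 58.9 ± 4.33 CPM (edgeR adjusted p = 0.0194). That call of Cbln1 was lost in 5 of the 9 fits that left out 1 library, with an edgeR adjusted p of up to 0.0801.

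**Figure D2:**
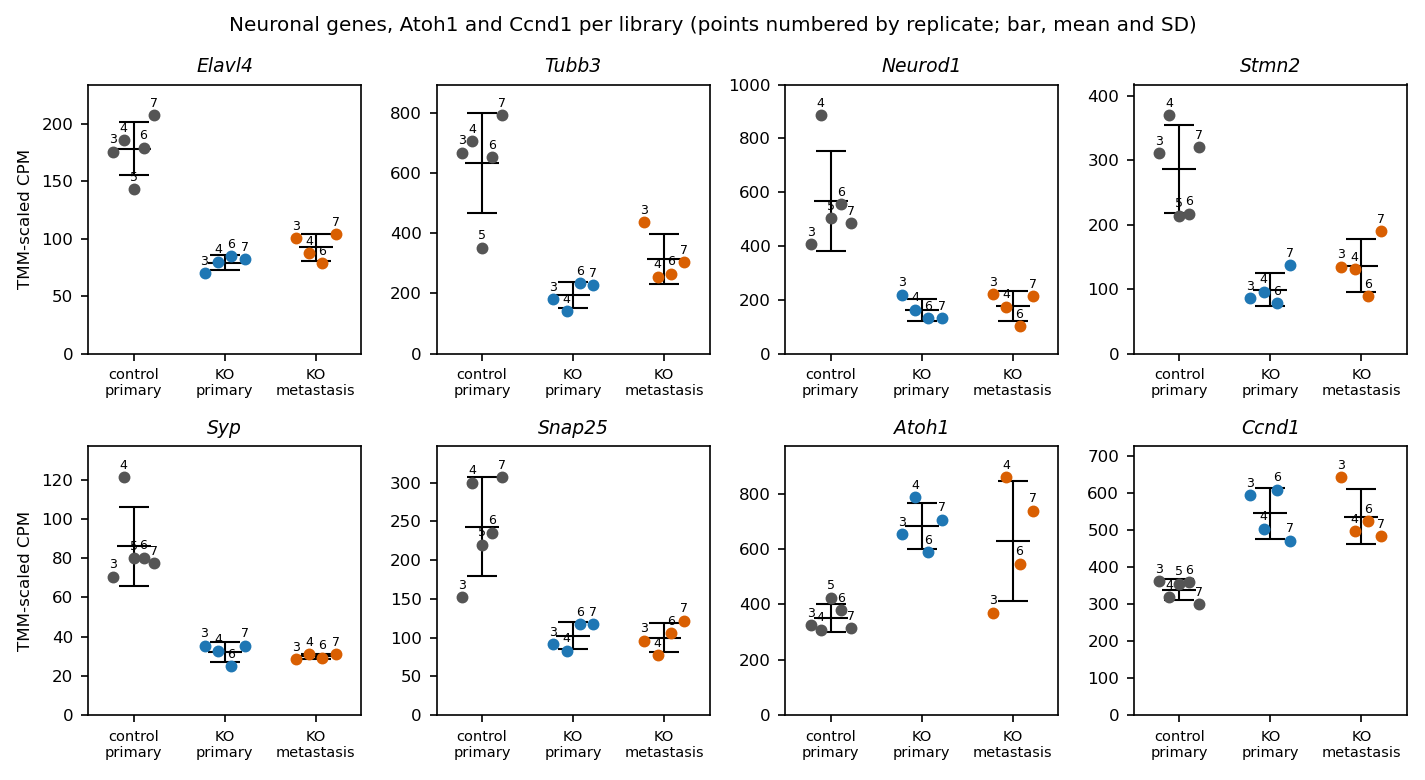
TMM-scaled CPM (vertical axes, from 0) of 8 genes in control primary, KO primary and KO metastasis libraries; points are libraries numbered by replicate, bars the mean and SD of each group. Elavl4, Tubb3, Neurod1, Stmn2, Syp and Snap25 had group means of 178, 633, 567, 286, 86.0 and 243 CPM in control primary and 79.1, 195, 162, 99.2, 32.0 and 102 CPM in KO primary tumours, while Atoh1 and Ccnd1 were higher in KO primary tumours.

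Hedgehog pathway genes were shifted upward as a list (median log2 change 0.39, camera adjusted p = 5.51e-05, adjusted p = 0.375 with an estimated correlation). Of 15 measured, 2 rose, Ccnd1 and Gas1, and 13 were not called (5 higher adjusted over the list alone). Gas1, a co-receptor for the Hedgehog ligand, rose from 89.5 ± 7.24 to 221 ± 77.9 CPM (edgeR adjusted p = 0.0122, and 0.0598 and 0.0631 without KO primary 3 and 4). Hhip, a Hedgehog target, stood at 94.4 ± 42.0 against 44.0 ± 17.5 CPM without a call (edgeR adjusted p = 0.162). Granule cell precursor identity genes had 2 of 12 members higher, 1 lower and 9 not called (4 higher and 1 lower adjusted over the list alone). Their median was 0.16 (camera adjusted p = 0.0317, adjusted p = 0.375 with an estimated correlation). Atoh1 (chromosome 6, 64729125 to 64731245) was among the higher members. Mfap4, a microfibril-associated glycoprotein, fell from 73.9 ± 32.2 to 17.0 ± 4.33 CPM (edgeR adjusted p = 0.00333). Atoh1 had an edgeR adjusted p of 0.0637, 0.0587, 0.0614 and 0.0953 without control primary 4, control primary 7, KO primary 3 and KO primary 4. The call of the list was lost without control primary 3 (camera adjusted p = 0.0956), control primary 5 (0.0609), KO primary 3 (0.0732) or KO primary 4 (0.0515).

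All 25 G1/S and DNA replication genes had a positive fold change (median 0.33, camera adjusted p = 1.47e-06, adjusted p = 0.375 with an estimated correlation). Of 21 G2/M and mitosis genes 20 did (median 0.26, camera adjusted p = 6.08e-04, adjusted p = 0.443 with an estimated correlation). No member of either list was called, over all genes or adjusted over the list alone. Cdt1, a replication licensing factor, stood at 166 ± 18.5 against 116 ± 10.6 CPM (edgeR adjusted p = 0.0615). Mcm6, part of the replicative helicase, stood at 796 ± 120 against 531 ± 108 CPM and Aurkb, a mitotic kinase, at 263 ± 21.9 against 201 ± 20.5 CPM (edgeR adjusted p = 0.224 and 0.119). MHC class I presentation genes had 3 of 16 members higher and 13 not called (5 higher and 1 lower adjusted over the list alone). Their median was 0.62 (camera adjusted p = 3.86e-04, adjusted p = 0.332 with an estimated correlation). H2-T23 rose from 6.56 ± 3.21 to 22.9 ± 5.39 CPM (edgeR adjusted p = 0.00811) and H2-Q7 from 0.222 ± 0.230 to 4.88 ± 0.919 CPM (edgeR adjusted p = 8.86e-04). H2-Q7 has near-identical neighbours whose reads cannot be told from its own, so its level is uncertain. Tap2, the other member called (edgeR adjusted p = 0.0444), lost its call in 8 of the 9 fits that left out 1 library.

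Matrix proteases and inhibitors were lower as a list (1 of 23 measured higher, 5 lower, 17 not called, 3 higher and 8 lower adjusted over the list alone). Their median was -0.53 (camera adjusted p = 0.0106, adjusted p = 0.375 with an estimated correlation). The membrane-bound metalloprotease gene Mmp24 fell from 195 ± 72.9 to 57.1 ± 20.7 CPM (edgeR adjusted p = 0.0175, and 0.0888 and 0.0790 without KO primary 4 and 6). The stromelysin Mmp11 rose from 6.89 ± 1.23 to 14.0 ± 2.93 CPM (edgeR adjusted p = 0.0121, and 0.0677 and 0.0522 without KO primary 3 and 6). The list itself had a camera adjusted p of 0.0716 and 0.0697 without KO primary 6 and 7. Targets of p53 had 1 of 20 members lower and 19 not called (2 lower adjusted over the list alone; median -0.22, camera adjusted p = 0.0351, adjusted p = 0.375 with an estimated correlation). The gene was Btg2, an antiproliferative gene, at 71.4 ± 15.7 against 148 ± 33.6 CPM (edgeR adjusted p = 0.0196, up to 0.0751 with 1 library left out). The call of the p53 list was lost without control primary 3, control primary 5 or KO primary 7 (limma camera adjusted p = 0.175, 0.0799 and 0.168). Immediate early and heat shock genes, which respond to dissociation, had none of 20 members called, also adjusted over the list alone. Of these, 14 had a positive fold change, with a median of 0.58 (camera adjusted p = 0.0106, adjusted p = 0.444 with an estimated correlation, and 0.103 without KO primary 6). Egr1 stood at 631 ± 324 against 240 ± 142 CPM in that list (edgeR adjusted p = 0.108).

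Hox genes, which mark hindbrain and spinal positions, were near absent from control primary tumours. Of the 28 genes listed 5 were measured, and 2 of them rose (4 adjusted over the list alone; camera adjusted p = 1.98e-05, adjusted p = 0.114 with an estimated correlation). Hoxa2, Hoxb2, Hoxb3 and Hoxb4 passed the low-count filter only through knockout libraries. The filter thus favoured a rise of the measured Hox genes against the controls, and the list test is no independent support for it. Limma voom with quality weights did not call the list (camera adjusted p = 0.0517, median 6.05). Nor was it called with the Xist level as a covariate (0.116, median 4.64) or without the 3 controls with Xist counts (0.143). That last fit tested 28131 genes, and its median of -0.26 covered Hox genes beyond these 5. In the controls left there, 3 and 4, Hoxa2 stood at 0.114 and 0 CPM and Hoxb4 at 0 and 0.03 CPM. The median log2 change of the 5 measured genes was 6.33 as fitted. It was 5.78 with Hoxa2 and Hoxb4 at their ratio of CPM and Hoxb3 at its bound. Hoxa2 rose from 3 counts over the 5 controls to 284 over the 4 KO primary libraries, a ratio of CPM of 97.6 (95% counting interval 33.1 to 476). Its edgeR adjusted p was 0.0158, and it was 0.0501 without control primary 4 and 0.0633 without KO primary 4. Hoxb4 rose from 1 count to 157, a ratio of 162 (28.6 to 6436; edgeR adjusted p = 0.0199, up to 0.106 with 1 library left out). Hoxb3 had 0 counts in the controls and 160 in KO primary libraries, at least 55.0-fold higher against a floor of 3 counts over the group, but was not called (edgeR adjusted p = 0.0906).

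Among markers of other cells, microglia and macrophages had no member called, also adjusted over the list alone. All 15 measured of 16 had a negative fold change (median -1.85, camera adjusted p = 6.33e-05, adjusted p = 0.441 with an estimated correlation). C1qa stood at 0.814 ± 0.906 against 5.49 ± 4.41 CPM. Oligodendrocyte markers had 1 of 11 lower (2 adjusted over the list alone; median -1.58, camera adjusted p = 9.73e-05, adjusted p = 0.375 with an estimated correlation). That gene, Opalin, had 0 counts in KO primary tumours and 118 in the controls, at least 38.1-fold lower. Its call was lost in 3 of the 5 fits without 1 library that could test it. Oligodendrocyte precursor markers had 1 of 10 lower and 9 not called (1 higher and 6 lower adjusted over the list alone). Their median was -1.003 (camera adjusted p = 0.00126, adjusted p = 0.353 with an estimated correlation, and 0.0795 without KO primary 7). C1ql1 was the called gene, at 514 ± 91.1 against 890 ± 161 CPM (edgeR adjusted p = 0.0186, up to 0.0832 with 1 library left out). Erythroid markers had 1 of 7 measured lower (3 adjusted over the list alone; median -1.03, camera adjusted p = 0.0164, adjusted p = 0.375 with an estimated correlation).

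The other 27 lists were not called as lists, though some held called genes. In brackets stands the limma camera adjusted p of each list. Axon guidance and neuronal migration (0.661) held 2 higher and 3 lower genes, among them Cxcl12, a chemokine, which fell from 32.7 ± 6.91 to 12.5 ± 1.02 CPM. The Notch pathway (0.731) held 2 higher genes, among them Jag1, and 2 lower, among them Dll4, and Wnt pathway targets (0.0904) Nkd1 higher and Sp5 lower. The BMP and TGF-beta response (0.650) held Id2, which rose from 151 ± 27.8 to 445 ± 121 CPM. Collagens and extracellular matrix (0.998) held 3 higher, among them Col4a1, and Sparc lower. Epithelial-mesenchymal transition (0.139) held Vim higher, integrins and cell adhesion (0.0519) L1cam lower and growth factors and receptor tyrosine kinases (0.126) Fgf5 higher and Ntrk2 lower. Cyclin-dependent kinase inhibitors (0.930) held Cdkn1c higher, hypoxia and glycolysis (0.339) Aldoa lower and the interferon response (0.209) Ifih1 higher. The lists of methylation enzymes of H3K4 and H3K27 (0.513), oxidative phosphorylation (0.782), genes of group 3 and group 4 medulloblastoma (0.520) and mitochondrially encoded transcripts (0.147) held no called gene. Of the marker lists, astrocytes and Bergmann glia (0.165) held Sox9 higher and Aqp4 lower, pericytes and mural cells (0.147) Abcc9 and Kcnj8 higher and ependymal and choroid plexus cells (0.164) Clic6 lower. Purkinje cells (0.661) held Pvalb higher, and spinal motor and cholinergic neurons (0.936) 2 genes higher, among them Slc5a7, and Slc18a3 and Ret lower. Lymphocytes (0.591), neutrophils (0.981), endothelial cells (0.7005), fibroblasts and meningeal cells (0.579), Schwann cells (0.407), unipolar brush cells (0.591) and skeletal muscle (0.661) held none. Of the genes named in this paragraph, Jag1 and L1cam lost their call in 1 of the 9 fits that left out 1 library, Kcnj8 in 3, Sparc, Ntrk2, Ifih1 and Abcc9 in 4, Aqp4 in 6, Clic6 and Pvalb in 7 and Col4a1, Sp5 and Slc18a3 in 8.

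Among genes whose libraries did not overlap between the groups (chance separates 4 from 5 libraries in 1.59% of genes), the largest rises were in Tpm3-rs7, Emilin2, Clrn1, Peg12, Egr3, Fgf5, Tnfaip6, Grb10, RP23-95H5.1, Nptx1, Scara3 and Gsto1. Clrn1 (chromosome 3, 58844028 to 58885340), which codes for the membrane protein clarin 1, rose from 1.11 ± 0.370 to 21.8 ± 1.44 CPM (log2 change 4.29, SE 0.24, edgeR adjusted p = 8.57e-07). Peg12 (chromosome 7, 62461871 to 62464510), an imprinted gene, rose from 0.921 ± 0.659 to 17.3 ± 3.26 CPM. Fgf5, a growth factor gene (chromosome 5, 98254184 to 98277030), rose from 7.76 ± 3.85 to 81.3 ± 55.8 CPM. Tpm3-rs7 (chromosome 14, 113314608 to 113316754) rose from 2.85 ± 0.758 to 89.0 ± 6.06 CPM. It is a near-identical copy of Tpm3 (chromosome 3, 90072649 to 90100902), which fell from 319 ± 33.5 to 226 ± 19.97 CPM, so its level is uncertain. The sum of both was 322 ± 33.6 CPM in control and 315 ± 26.0 CPM in KO primary tumours. The largest falls were in Prrt1, Slc18a3, Pnoc, Nxph4, Neurod2, Slc15a2, Ret, Dnm1, Sncb, Plch2, Ssc5d and Csdc2. Pnoc, the precursor of the neuropeptide nociceptin (chromosome 14, 65400673 to 65425472), fell from 27.7 ± 12.3 to 0.965 ± 0.917 CPM (log2 change -4.84, SE 0.709, edgeR adjusted p = 0.00212). Csdc2 (chromosome 15, 81936759 to 81950941) fell from 47.0 ± 7.69 to 3.51 ± 1.01 CPM, and Neurod2 from 11.2 ± 5.72 to 0.525 ± 0.413 CPM. Of these 24 genes 17 stayed called whichever library was left out. Slc18a3, Gsto1, Slc15a2, Plch2, RP23-95H5.1, Nptx1 and Egr3 lost their call in 8, 7, 6, 6, 3, 2 and 1 of the 9 fits.

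The count of 653 was 277, 327 and 340 without KO primary 4, 6 and 3, 340 and 412 without control primary 4 and 7, and 1032 without control primary 3. It was 230 with the Xist level as a covariate, 138 without the 3 controls with Xist counts, 1427 without the 4 high-background libraries and 1090 with their receptor level as a covariate. The fit that gave 138 kept only control primary 3 and 4 as controls, and control primary 3 is a high-background library. That count therefore does not isolate sex. DESeq2 called 1665 and limma voom with quality weights 3267 genes, of which 50.1% were higher in place of 39.4%.

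The second comparison set spinal metastases against primary tumours of the same genotype. Mbp (chromosome 18, 82475146 to 82585637), which codes for myelin basic protein, was the only gene called by edgeR. It rose from 44.2 ± 8.03 CPM (n = 4) in KO primary to 246 ± 117 CPM (n = 4) in KO metastasis libraries (log2 change 2.47, SE 0.318, edgeR adjusted p = 0.0485). At an unadjusted p below 0.05 edgeR gave 720 genes, where chance gives 1113. DESeq2 called 39 genes, limma voom with quality weights 2, edgeR without a low-count filter 2 (Mbp and Mobp) and edgeR fitted to these 2 groups alone 0, with 624 at an unadjusted p below 0.05. The call of Mbp was lost without any of the KO primary libraries 3, 4, 6 and 7 (edgeR adjusted p = 0.170, 0.463, 0.480 and 0.355) or without KO metastasis 4, 6 or 7 (0.144, 0.0684 and 0.0948). It was also lost with the 2 groups fitted alone (0.123), without the 4 high-background libraries (0.104) and with their receptor level as a covariate (0.0608). With the replicate numbers as a block, though they were not taken to pair the libraries, edgeR called 0 genes.

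Oligodendrocyte markers were higher as a list, with 11 of 11 fold changes positive, 1 member called by edgeR, 10 adjusted over the list alone and a median log2 change of 4.69 (camera adjusted p = 3.42e-25, adjusted p = 0.0700 with an estimated correlation). The rise differed between libraries. Mbp was at 134, 251, 406 and 191 CPM in KO metastasis 3, 4, 6 and 7 and between 38.9 and 55.9 CPM in KO primary libraries. Mobp, another myelin gene, was at 9.59, 29.9, 78.0 and 28.1 CPM against 0.443 to 1.95 CPM. Microglia and macrophage markers had 15 of 15 measured members positive, none called by edgeR and 11 called adjusted over the list alone (median 3.36, camera adjusted p = 1.90e-27, adjusted p = 0.0744 with an estimated correlation). DESeq2 called 7 of them, C1qa, C1qb, C1qc, Csf1r, Ctss, P2ry12 and Tmem119. C1qb was at 8.30, 2.07, 41.7 and 32.7 CPM in KO metastasis 3, 4, 6 and 7. KO metastasis 6 and 7, where C1qb was highest, are also 2 of the high-background libraries. Schwann cell markers, which include Mbp, had a median of 0.55 (camera adjusted p = 3.93e-04, adjusted p = 0.181 with an estimated correlation, and 0.0800 without KO metastasis 6 and 0.957 without the 4 high-background libraries). Erythroid markers had a median of 0.87 with no member called (camera adjusted p = 0.0113, adjusted p = 0.513 with an estimated correlation). This call was lost without KO primary 6 (0.0503) or 7 (0.0613) and without KO metastasis 3 (0.0941) or 6 (0.0801).

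Immediate early and heat shock genes had 20 of 20 fold changes positive, none called by edgeR (Klf2 by DESeq2) and 8 called adjusted over the list alone (median 0.81, camera adjusted p = 4.52e-19, adjusted p = 0.0579 with an estimated correlation). Jund stood at 113 ± 40.7 against 63.7 ± 16.6 CPM and Nr4a1, a nuclear receptor gene of the early response, at 11.7 ± 3.56 against 4.34 ± 1.49 CPM, without a call. Mitochondrially encoded transcripts had 10 of 10 measured members positive and 8 called adjusted over the list alone (median 0.65, camera adjusted p = 1.95e-10, adjusted p = 0.156 with an estimated correlation). In this list mt-Nd5 stood at 522 ± 131 against 373 ± 33.0 CPM without a call, beside the high mitochondrial share of KO metastasis 3. Levels of mitochondrial genes with nuclear copies are uncertain. Hox genes had a median of 3.00 (4 of 5 called adjusted over the list alone, none over all genes; camera adjusted p = 3.93e-04, adjusted p = 0.131 with an estimated correlation, and 0.690 by limma voom with quality weights). Hoxa2 was at 13.2, 13.2, 5.13 and 11.5 CPM in KO metastasis 3, 4, 6 and 7 and at 1.56, 4.71, 1.35 and 0 CPM in KO primary 3, 4, 6 and 7. Hoxb4 was at 32.4, 12.6, 8.01 and 0.115 CPM against 1.04, 1.03, 1.72 and 0.379 CPM.

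Oligodendrocyte precursor markers were lower, with 9 of 10 fold changes negative, none called by edgeR and a median of -0.65 (camera adjusted p = 2.16e-04, adjusted p = 0.131 with an estimated correlation). Pdgfra, the receptor of these precursors, stood at 89.1 ± 31.4 against 158 ± 16.1 CPM. No member of the 5 other called lists was called by edgeR, also adjusted over the list alone. They were the mature granule neuron and synapse genes (median -0.56, camera adjusted p = 0.00233, adjusted p = 0.574 with an estimated correlation, and 0.0854 without KO primary 7) and the early granule neuron genes (median 0.18, 0.00516, adjusted p = 0.530 with an estimated correlation, and 0.0613 without KO primary 7 and 0.135 without KO metastasis 3). The others were the Hedgehog pathway (median -0.30, camera adjusted p = 0.0106, adjusted p = 0.608 with an estimated correlation), G1/S and DNA replication (median -0.13, 0.00540, adjusted p = 0.640 with an estimated correlation) and oxidative phosphorylation (median 0.18, 0.00675, adjusted p = 0.770 with an estimated correlation). The Hedgehog call was lost without KO primary 3 (0.427), KO metastasis 6 (0.197) or KO metastasis 7 (0.156) and the G1/S call without KO metastasis 3 (0.373) or 6 (0.204). The oxidative phosphorylation call was lost without KO primary 7 (0.879) or KO metastasis 3 (0.828). Without the 4 high-background libraries edgeR called 5 genes, all higher and none of them Mbp: Ren1, Rcan2, Hoxb3, Hoxb4 and Map1b, which are named here after their values were seen.

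**Figure D3:**
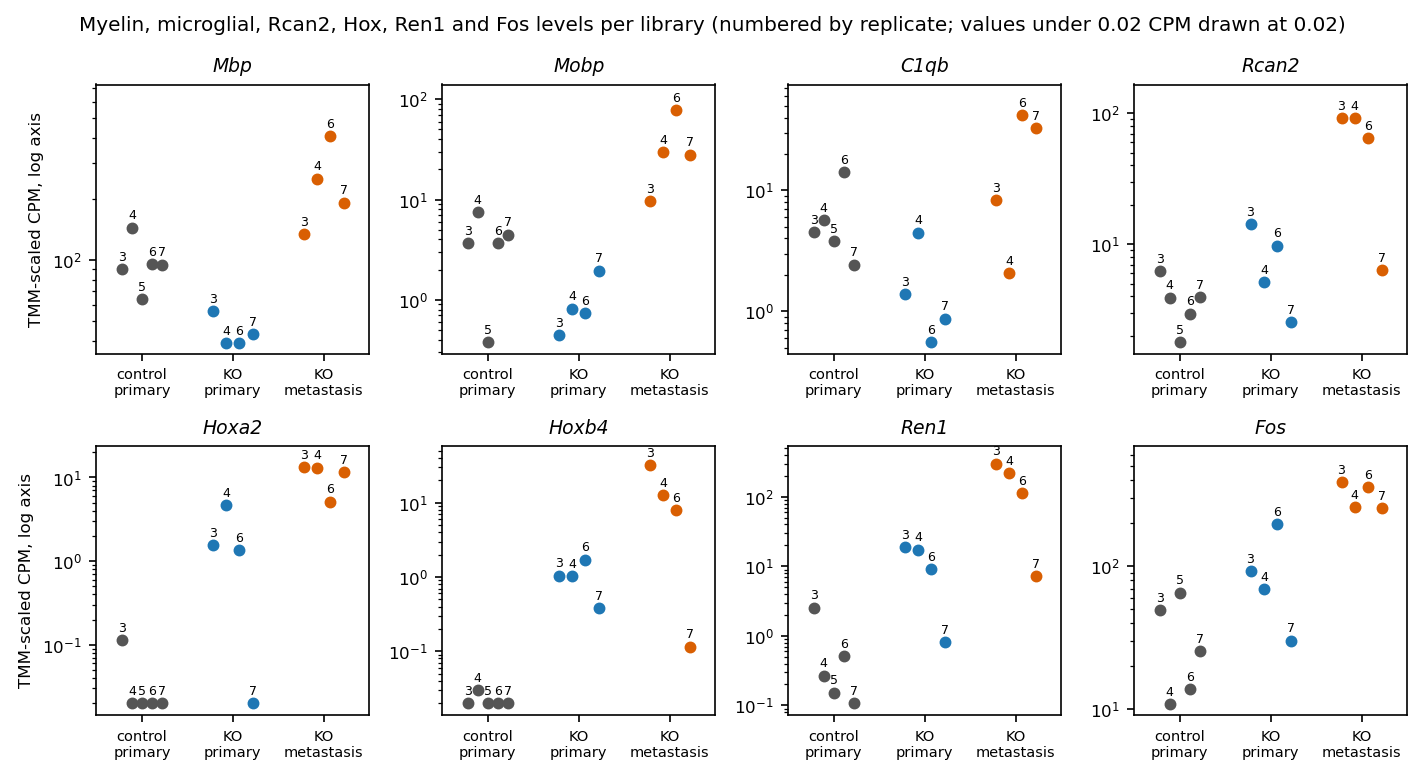
TMM-scaled CPM on log axes (vertical) of 8 genes in control primary, KO primary and KO metastasis libraries, each point a library numbered by replicate, with values under 0.02 CPM drawn at 0.02. C1qb was at 8.30, 2.07, 41.7 and 32.7 CPM and Ren1 at 299, 221, 114 and 7.28 CPM in KO metastasis 3, 4, 6 and 7.

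The third comparison set spinal metastases of the knockout against control primary tumours, so genotype and site differ together. Early response genes were higher and neuronal genes lower in the metastases. Fos, a transcription factor of the immediate early response, rose from 33.0 ± 23.5 CPM (n = 5) to 314 ± 67.6 CPM (n = 4), a log2 change of 3.26 (SE 0.565, edgeR adjusted p = 0.00616). Syp fell from 86.0 ± 20.2 to 30.0 ± 1.16 CPM (edgeR adjusted p = 4.08e-04). Ren1 (chromosome 1, 133350510 to 133360325), the renin gene, rose from 0.718 ± 1.03 to 160.1 ± 127 CPM (log2 change 7.86, SE 1.22, edgeR adjusted p = 0.00316). In all, 685 of 22265 genes changed at an edgeR adjusted p below 0.05, 235 higher and 450 lower, 516 of them by at least 2-fold (156 higher, 360 lower). At an unadjusted p below 0.05 there were 3170, against 1113 by chance.

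Immediate early and heat shock genes had 8 of 20 members higher, none lower and 12 not called (12 higher adjusted over the list alone; median 1.79, camera adjusted p = 6.38e-16, adjusted p = 0.0335 with an estimated correlation). Egr1 rose from 240 ± 142 to 1173 ± 150 CPM (edgeR adjusted p = 0.0104). Fosb rose from 3.04 ± 3.90 to 43.8 ± 24.6 CPM (edgeR adjusted p = 0.0165, and 0.0577 without KO metastasis 3). Hox genes had 4 of 5 measured members higher (4 adjusted over the list alone; camera adjusted p = 7.86e-08, adjusted p = 0.0335 with an estimated correlation, and 0.0607 by limma voom with quality weights). Here too the low-count filter favoured a rise, since Hoxa2, Hoxb2, Hoxb3 and Hoxb4 passed it only through knockout libraries. The median was 8.82 as fitted and 9.14 with Hoxa2 and Hoxb4 at their ratio of CPM and Hoxb3 at its bound. Without the 3 controls with Xist counts camera still called the list, in a fit of 28131 genes. The median there was -0.66 but covered Hox genes beyond these 5. Hoxa2 (chromosome 6, 52162417 to 52164831) rose from 3 to 1409 counts, a ratio of CPM of 564 (95% counting interval 193 to 2737). Hoxb3 (chromosome 11, 96323326 to 96347930) rose from 0 to 1623 counts, at least 649-fold. Early granule neuron genes had 8 of 20 members lower, none higher and 12 not called (11 lower and 1 higher adjusted over the list alone; median -0.63, camera adjusted p = 1.63e-12, adjusted p = 0.0451 with an estimated correlation). Among them Cntn1, a neuronal adhesion molecule, fell from 34.3 ± 10.7 to 7.12 ± 2.62 CPM and Elavl4 from 178 ± 23.2 to 92.4 ± 11.8 CPM. Oligodendrocyte precursor markers had 5 of 10 lower and 5 not called (7 lower adjusted over the list alone; median -1.29, camera adjusted p = 2.24e-08, adjusted p = 0.0335 with an estimated correlation). Cspg4, the NG2 proteoglycan gene, fell from 16.6 ± 3.99 to 3.96 ± 0.894 CPM (edgeR adjusted p = 0.00508) and C1ql1 from 890 ± 161 to 416 ± 52.9 CPM (edgeR adjusted p = 0.00276).

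The other 11 called lists lost their call with an estimated correlation. Mature granule neuron and synapse genes had 7 of 25 lower, 1 higher and 17 not called (17 lower and 1 higher adjusted over the list alone; median -1.28, camera adjusted p = 7.88e-13, adjusted p = 0.0915 with an estimated correlation). Nrxn3, a synaptic adhesion molecule, fell from 13.7 ± 5.12 to 2.69 ± 0.679 CPM, and Cbln1 was the higher member. MHC class I presentation genes had 2 of 16 higher (5 adjusted over the list alone; median 0.42, camera adjusted p = 2.39e-04, adjusted p = 0.123 with an estimated correlation). Precursor identity genes had 3 of 12 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.37, camera adjusted p = 0.00310, adjusted p = 0.300 with an estimated correlation). Barhl1, a homeobox gene of granule precursors, rose from 714 ± 144 to 1302 ± 260 CPM (edgeR adjusted p = 0.0106). Ependymal and choroid plexus markers had 2 of 7 measured lower (2 adjusted over the list alone; median -1.57, camera adjusted p = 0.0225, adjusted p = 0.123 with an estimated correlation, and 0.0529 without KO metastasis 3). Targets of p53 had a median of -0.36 (camera adjusted p = 0.0225, adjusted p = 0.367 with an estimated correlation, and 0.124 without control primary 3). The medians of G1/S, G2/M and Hedgehog genes were 0.19, 0.22 and 0.20 (camera adjusted p = 0.00492, 0.00512 and 0.0243, each with adjusted p = 0.705 with an estimated correlation). Without KO metastasis 4 these 3 calls were lost (0.179, 0.0972 and 0.226), and without control primary 3 those of G2/M (0.101) and Hedgehog genes (0.265). Of the members of these 4 lists Ccnd1 was the only one called, with edgeR adjusted p = 0.00976 and 0.0517 without KO metastasis 3.

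Among markers of other cells, 2 of 11 oligodendrocyte genes rose, Mbp and Mobp (6 adjusted over the list alone). Leaving out 1 library ended the call of Mbp in 4 and of Mobp in 3 of 9 fits (edgeR adjusted p up to 0.0754 and 0.0755). The list median was 2.39 (camera adjusted p = 0.0104, adjusted p = 0.705 with an estimated correlation, and 0.281 without KO metastasis 6). It was -1.33 without the 4 high-background libraries, which left only KO metastasis 3 and 4 of the metastases. Microglia and macrophage markers had a median of 1.53 with no member called (camera adjusted p = 0.00459, adjusted p = 0.705 with an estimated correlation). Without KO metastasis 6 and 7 the camera adjusted p was 0.123 and 0.0576, and without the 4 high-background libraries the median was -0.59. Mitochondrially encoded transcripts (median 0.44, camera adjusted p = 0.0342, adjusted p = 0.705 with an estimated correlation) were not called without KO metastasis 3 (0.601), control primary 3 (0.183) or control primary 7 (0.0753).

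Genes with the largest rises and no overlap between the groups included Hoxb4, Ren1, Tpm3-rs7, RP23-338O4.6, Egr3, Emilin2, Peg12, RP24-402O2.2, Rcan2, Clrn1 and Fosb. Those with the largest falls were Cbln3, Slc18a3, Prrt1, Neurod2, Pnoc, Krt12, RP23-336D20.8, Dnm1, Plch2, Sncb, Csdc2 and Slc15a2. Of the 24 genes with the largest rises and falls 17 stayed called whichever library was left out. RP23-336D20.8, Slc15a2, Cbln3, Plch2, Slc18a3, Krt12 and Fosb lost their call in 7, 7, 5, 5, 4, 2 and 1 of the 9 fits. Rcan2, a regulator of calcineurin, rose from 3.77 ± 1.64 to 63.7 ± 40.4 CPM (edgeR adjusted p = 0.00447), with 92.2, 92.1, 64.4 and 6.33 CPM in KO metastasis 3, 4, 6 and 7. Ren1 was at 299, 221, 114 and 7.28 CPM in those metastases and at 18.99, 17.3, 9.18 and 0.813 CPM in KO primary 3, 4, 6 and 7. The count of 685 was 369, 401 and 410 without KO metastasis 4, 6 and 3, 379, 428 and 436 without control primary 4, 7 and 6 and 1199 without control primary 3. It was 228 with the Xist level as a covariate, 100 without the 3 controls with Xist counts, 1274 without the 4 high-background libraries and 1099 with their receptor level as a covariate. The fit that gave 100 again kept only control primary 3 and 4 as controls. DESeq2 called 1639 and limma voom with quality weights 3822, of which 60.7% were higher in place of 34.3%.

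**Figure D4:**
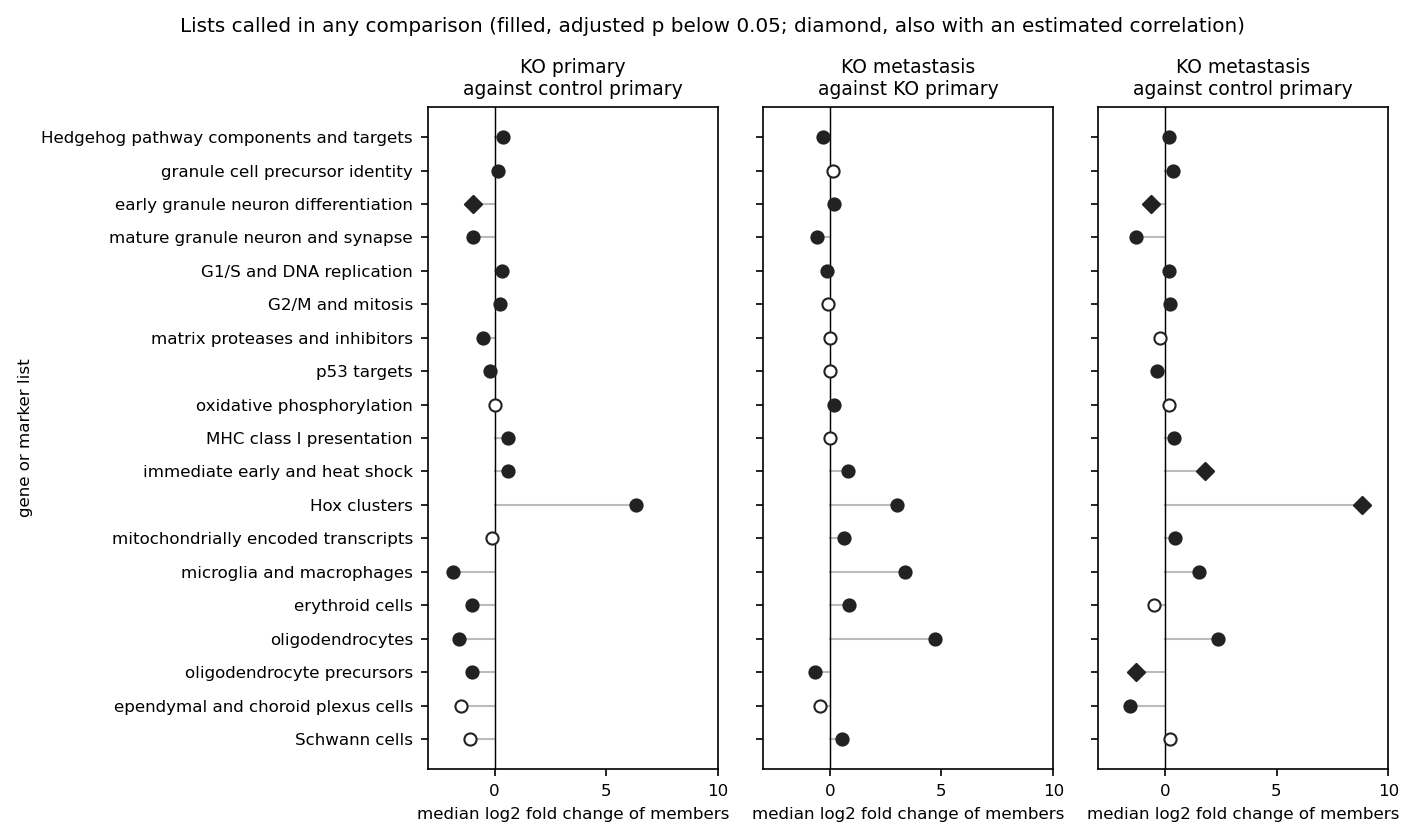
Median log2 fold change of the members (horizontal axes) of each list called in at least 1 of the 3 comparisons (vertical axis), filled where the camera adjusted p was below 0.05 and drawn as a diamond where it also was with an estimated correlation. Early granule neuron differentiation lay at -0.96 in KO primary and -0.63 in KO metastasis against control primary, and the oligodendrocyte median moved from -1.58 in KO primary against control primary to 4.69 in KO metastasis against KO primary.

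Both knockout groups were then compared through their changes against the same 5 controls, over 15097 genes with a mean of at least 1 CPM. Their p-values were adjusted over these genes alone. Of 810 genes called in KO primary and 861 in KO metastasis tumours, 188 were higher in both, among them Clrn1 and Peg12, 368 lower in both, among them Pnoc and Csdc2, and 1 went in opposite directions. Lists independent of each other would share 7.03 higher and 17.1 lower genes. Over all 22265 tested genes, with 653 and 685 called, 139 were higher in both, 308 lower in both and 0 opposite. Across genes, which are not independent replicates, the fold changes had a covariance of 0.424 and a correlation of 0.774. With all libraries simulated without a change, controls included, the covariance was 0.106 and the correlation 0.442. Drawn gene by gene, the simulated libraries did not carry the sex and background differences of the real ones. The observed covariance lay 0.318 above the simulated one. With the controls split between the comparisons, over 20 splits the mean overlap was 15 higher and 59.1 lower genes, where independent lists give 0.325 and 2.17. The covariance was 0.289 ± 0.0360 (SD over splits) with a correlation of 0.386.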

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

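The tests of myelin genes and of reads shared with Tpm3 in this part were chosen only after those results were seen, and the setting without the high-background libraries was added after the data were seen.

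Early granule neuron differentiation genes were lower in KO primary than in control primary tumours, with a median log2 change of -0.96 over 20 genes (-1.01 to -0.90 with 1 library left out). With the Xist level as a covariate the median was -0.97 (-1.10 to -0.86 with 1 more library left out), and without the 4 high-background libraries it was -0.97 (-1.08 to -0.88), which argues against sex or background as the whole cause. With a camera correlation estimated from the data these settings gave adjusted p = 0.164 and 0.157, for a cause that was not tested, and 5 and 12 members were lower in place of 11. With the mean of 5 mature granule neuron markers as a covariate the median was -0.79 (-0.97 to -0.76, adjusted p = 0.0317 with an estimated correlation, 1 member lower), which argues against mature neurons in the sorted fraction as the whole cause. An effect of Kmt2d loss on differentiation may remain as a hypothesis, and age, 6 to 16 weeks in controls and 5 to 8 weeks in knockouts, stays open and untested because it differs between the groups.

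Myelin genes were higher in the metastases, in 2 different ways. In KO metastasis 6 and 7, 10 of 11 oligodendrocyte markers (all but Aspa) lay above the highest KO primary library, so oligodendrocytes or their RNA in the GFP sort may be a source there. In KO metastasis 3 and 4, 2 of the 11 oligodendrocyte markers did so, Mbp (134 and 251 CPM) and Mobp (9.59 and 29.9 CPM, against at most 1.95 CPM in KO primary libraries), which argues against whole oligodendrocytes in the sorted fraction there. Myelin fragments that carry Mbp and Mobp mRNA, with a lowest Mobp level of 9.59 CPM, and expression by the tumour cells themselves cannot be told apart, because no value here separates them.

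Between KO primary and control primary tumours 34 called genes differed at least 8-fold with groups that did not overlap, 32 of them with a position. Only 1 of the 32, Csdc2 (3.125%), lay within 20 Mb of Kmt2d, which argues against linkage to the targeted locus. At most 1 Mb apart lay 1 pair (median of 10000 random sets 1, highest 6, permutation p = 0.562), so the genes did not cluster at that distance. This cannot decide on blocks of another strain, since a block can be longer and hold 1 such gene. Prrt1 (chromosome 17, 34629533 to 34633126) is among the 34. H2-Q7 (chromosome 17, 35439155 to 35443773) and H2-T23 (chromosome 17, 36029773 to 36032855) were called but are not among them. For Tpm3-rs7 the sum with Tpm3 differed by -7.01 CPM while Tpm3-rs7 itself rose by 86.2 CPM (exact permutation p = 0.714 for the sum, 126 splits). Its rise may therefore be Tpm3 reads counted elsewhere, with Tpm3 lower in all 8 knockout libraries than in any control. A sequence variant of Tpm3 shared by the knockout mice, which would move such reads, and the effect of Kmt2d loss on the other genes stay open and were not tested.

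The grouping of the libraries was compared with other splits into groups of the same sizes. For KO primary against control primary a chance result is unlikely, since 1 of 100 splits, the real one, gave as many as 653 genes and the highest other gave 106. For KO metastasis against control primary it is unlikely too (1 of 100, 685 genes, highest other 514), and that other split set control primary 3 and the metastases against control primary 4 to 7. The smallest share that 100 splits can give is 1%. The splits treat libraries as independent, which the labels do not settle. For KO metastasis against KO primary chance cannot be excluded, since 3 of 35 splits gave at least the 1 gene called, and the highest other gave 23. That split set numbers 3 and 4 of both tissues against 6 and 7, which points to a structure of the samples. It follows the replicate numbers and also the background (83.5 to 723 receptor CPM in numbers 6 and 7, 6.08 to 10.7 in 3 and 4), so background and a mouse or batch shared by number stay open. Without the 4 high-background libraries the real split gave 5 genes, and with the receptor level as a covariate 0 by edgeR (1106 at an unadjusted p below 0.05, with 39 by DESeq2 and 2 by limma voom without that covariate).

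Single libraries stood far from the others of their group in 29 of 360 groups of values tested, where chance gives about 1 in 20 (18). Control primary 3 had 40295 genes with a count against 24131 to 25785, and 1752 receptor CPM against 11.9 to 19.5. KO primary 7 had 723 receptor CPM against 7.44 to 83.5. KO metastasis 3 had 2.06% of counts on mitochondrial genes against 0.745% to 0.860%. Rn18s-rs5, named as a related sequence of the ribosomal gene Rn18s, was at 4474 CPM in control primary 3 (others 1412 to 2228). It was at 11779 CPM in KO metastasis 3 (others 2135 to 3059). The 10 most abundant genes took 3.30% of counts in control primary 3 (others 2.34% to 2.54%) and 5.30% in KO metastasis 3 (others 2.57% to 2.64%).

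Of gene levels, Nptx1 was at 770 CPM in KO primary 3 (others 151 to 180), Sncb at 1.63 CPM in KO primary 7 (0.408 to 0.521) and Slc18a3 at 1.11 CPM in KO metastasis 3 (others 0). Tubb3 was at 351 CPM in control primary 5 (652 to 790) and Syp at 121 CPM in control primary 4 (70.7 to 80.3). Gas1 was at 260 CPM in KO metastasis 4 (127 to 132) and Barhl1 at 1098 CPM in KO primary 4 (922 to 939). Hoxa2 was at 0.114 CPM in control primary 3 (others 0) and 5.13 CPM in KO metastasis 6 (11.5 to 13.2), Hoxb2 at 0.190 CPM in control primary 3 and Hoxb4 at 0.0296 CPM in control primary 4 (others 0 for both). Dll4 was at 4.20 CPM in KO primary 7 (1.41 to 1.59). Pdgfra was at 181 CPM (147 to 151) and Cxcl12 at 10.9 CPM (12.9 to 13.01) in KO primary 3. Rcan2 was at 6.33 CPM in KO metastasis 7 (64.4 to 92.1), Isl1 at 0.290 CPM in control primary 6 (0 to 0.0380) and Cox5b at 145 CPM in control primary 3 (80.2 to 90.1). As mean log2 CPM of a list, Hox genes were at -0.53 (-1 to -0.98) and oxidative phosphorylation at 7.60 (7.02 to 7.15) in control primary 3. Oligodendrocyte precursor markers were at 4.99 in KO primary 6 (4.38 to 4.43) and ependymal markers at 1.14 in KO primary 7 (0.57 to 0.61).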

How the results depend on the processing

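The settings without the high-background libraries, with the receptor level as a covariate and without the 3 controls with Xist counts were chosen after the data were seen. Refits were counted for the called genes named here and for Kmt2d and Smo, which were never called. Of those that left out 1 library, 1117 gave the same result, 262 lost the call and 0 reversed. In the other settings the numbers were 1347, 259 and 0. The same result means direction and call kept or, for Kmt2d and Smo, again no call. For called lists the numbers were 335, 39 and 0 with 1 library left out, and 256, 115 and 3 in the other settings, by the direction of the list test.

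For KO primary against control primary, KO metastasis against KO primary and KO metastasis against control primary, edgeR called 653, 1 and 685 genes. DESeq2 called 1665, 39 and 1639, and limma voom with quality weights 3267, 2 and 3822. Without a low-count filter KO metastasis against KO primary gave 2 genes. With the Xist level as a covariate the 2 comparisons with control primary gave 230 and 228, and without the 3 controls with Xist counts 138 and 100. The latter fits kept only control primary 3, a high-background library, and control primary 4 as controls. Without the 4 high-background libraries the 3 comparisons gave 1427, 5 and 1274 genes, and with the background covariate 1090, 0 and 1099. With 1 library left out the counts ran from 277 (without KO primary 4) to 1032 (without control primary 3), from 0 (without KO primary 3, for example) to 1 (without KO metastasis 3) and from 369 (without KO metastasis 4) to 1199 (without control primary 3). A fit of the 2 compared groups only gave 0 genes for KO metastasis against KO primary (624 at an unadjusted p below 0.05 by edgeR). The causes were not tested, beyond the smaller number of libraries where some were left out.

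Replicate numbers were not taken to pair the libraries, and whether a number marks a shared mouse stays open. Between metastases and KO primary tumours, numbers 6 and 7 correlated best with their own number (0.343 and 0.579), while 3 and 4 did not (-0.0135 and 0.150). Groups of different genotype cannot share a mouse. Yet number 3 of KO metastasis and control primary (0.369) and number 7 of KO primary and control primary (0.263) also matched best. The remaining numbers of those comparisons did not. The 0.343 is therefore no hint of a shared mouse, and the 0.579 is a hint only. With the replicate block edgeR called 0 genes in that comparison (633 at an unadjusted p below 0.05), and Mbp had an edgeR adjusted p = 0.201.

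Of lists, 15, 13 and 15 were called, and with 1 library left out 13 to 17, 10 to 15 and 12 to 16. Camera with an estimated correlation called 1, 0 and 4, and fry 3, 0 and 10. For KO metastasis against control primary, limma voom with quality weights called 8 lists, and without the 4 high-background libraries 7 were called. In that last setting the medians of microglia and macrophages and of oligodendrocytes reversed to -0.588 and -1.33. Of the metastases it keeps only KO metastasis 3 and 4. In KO metastasis 6 and 7, 10 of 11 oligodendrocyte markers lay above the highest KO primary library. C1qb was at 41.7 and 32.7 CPM there, against 8.30 and 2.07 CPM in KO metastasis 3 and 4. Marker content and background therefore cannot be told apart by this setting. Under limma voom with quality weights the median of oxidative phosphorylation between metastases and KO primary tumours reversed to -0.0071. The median changed sign in 3 more cases where the direction of the test did not. These were mitochondrially encoded transcripts between metastases and control primary under voom (-0.0028) and, without the 3 controls with Xist counts, Hox genes in KO primary and metastases against control primary (-0.26 and -0.66). The Hox medians came from a fit of 28131 genes and covered Hox genes beyond the 5 of the main fit. They are therefore no change of sign of those 5. With the control libraries split, the covariance of the changes of both knockout groups was 0.289 in place of 0.424. The causes were not tested. In counts simulated at this depth 31.3% to 40.3% of 2-fold changes were recovered.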

Other observations

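The imprinted list in this part was written after Peg12 and Grb10 had been seen among the largest rises, and without both genes.

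The following 5 genes, picked by hand, were called in both knockout groups against control primary tumours. Vim, an intermediate filament gene of progenitors and glia, rose from 138 ± 21.96 CPM (n = 5) to 356 ± 96.6 CPM in KO primary and 468 ± 188 CPM in KO metastasis libraries (n = 4 each, edgeR adjusted p = 0.00815 and 0.00186). Nkd1, a feedback inhibitor of Wnt signalling, rose from 318 ± 42.3 to 714 ± 63.4 and 570 ± 88.6 CPM (edgeR adjusted p = 5.72e-04 and 0.00413). Cdkn1c, an imprinted inhibitor of the cell cycle, rose from 11.98 ± 2.83 to 40.3 ± 12.95 and 50.1 ± 18.7 CPM (edgeR adjusted p = 0.00417 and 0.00157). Dll4, a Notch ligand, fell from 13.8 ± 3.03 to 2.19 ± 1.34 and 3.91 ± 0.286 CPM (edgeR adjusted p = 8.86e-04 and 0.00761). Ephb1, an axon guidance receptor, fell from 18.0 ± 6.38 to 3.05 ± 1.19 and 3.69 ± 1.23 CPM (edgeR adjusted p = 0.00253 and 0.00468). These 5 genes stayed called whichever library was left out, in both comparisons. Of them, only Ephb1 and Dll4 in KO primary and Ephb1 in KO metastasis also kept their call in every other setting, the replicate block not counted.

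A general rise of imprinted genes was a hypothesis raised by Peg12, Grb10 and Cdkn1c, of which Cdkn1c stayed in the list. Of 48 listed imprinted genes 42 were measured, and in KO primary tumours 2 were higher (Begain, Cdkn1c) and 1 lower (Nnat), with a median log2 change of -0.09. Camera with an estimated correlation gave p = 0.894 with the direction up, so no shift of the list was found. The median below 0 argues against a general rise. A change at single imprinted loci may remain as an explanation for Peg12 and Grb10 and was not tested.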
